A study of Mus musculus with 4 samples.

How the data were processed

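Single-cell RNA libraries of mouse skeletal muscle, made with the 10x Chromium 3' v3.1 chemistry per the labels, were deposited as 1 count matrix per library. The 4 libraries stood for 2 treatments (vehicle and LNP-CRISPR) in 2 isolations (bulk and satellite cell isolation kit), with 1 library per group. The deposited values are raw counts of UMIs per gene and barcode, all whole numbers. The matrix headers name cellranger 5.0.1, whereas the submitters' processing notes name Cell Ranger 7.0.1 and mm10. The matrices had already been limited to called cells by the authors. They held 6512 barcodes and 128987621 UMIs over 32286 features, of which 32285 were mouse genes and 1 was the added feature Cas9. Gene identifiers were matched to GENCODE M21 (32235 found, 99.8%), which gave the GRCm38 positions. Mx1 and Mx2 of the interferon list were not among the features.

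Choices of filters, cell markers, gene lists, comparisons and most alternatives were fixed before the data were examined. Barcodes with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, which removed 101, 165, 272 and 300 barcodes from vehicle bulk, LNP-CRISPR bulk, vehicle kit and LNP-CRISPR kit. Scrublet, as built into scanpy 1.11.5, was run per library at an expected doublet rate of 0.05. It called 5, 3, 7 and 8 doublets, 0.260% to 0.496% of cells, far below that rate, so doublets are treated as largely still present. The 5651 cells kept were scaled to 10000 UMIs, log-transformed, reduced to 2000 variable genes and 30 principal components, joined by 15 neighbours and clustered together by the Leiden method at resolution 1.0 (seed 1) without batch integration. A cluster took the name of the class among 16 marker lists whose markers were most enriched, if at least 3 markers had a log2 fold of at least 1 and were detected in at least 10% of its cells, and if its 10 leading genes did not hold more markers of another class. The added condition that the leading marker gene belong to the class came after the clusters had been seen and left 1 cluster of LNP-CRISPR bulk unnamed. Names end in "-like" because they rest on these markers alone. Median genes per kept cell were 4396, 3513, 2582.5 and 2969.

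Shares were given with exact binomial 95% intervals, and ratios of shares or expression with exact conditional binomial intervals. Expression in a class was the sum of UMIs over its cells per 1000000 nuclear-encoded UMIs (CPM), with exact Poisson intervals. No test was run and no p-value was computed, since cells of 1 library are not replicates. Classes with at least 50 kept cells in both libraries of an isolation were compared, and cluster 1 was compared by its number, a choice made after the clusters had been seen. No class reached 50 cells in all 4 libraries, so satellite-like expression was not compared between isolations. A count of 0 was set against a floor of 3 counts, which for Cas9 in the vehicle libraries was 0.0888 (bulk) and 0.105 (kit) CPM. Cas9 was also given as the share of cells with at least 4 UMIs, a limit set after the Cas9 counts had been seen, and as the share with a UMI after thinning to 1000 UMIs per cell. Cells with fewer than 1000 UMIs were left out wherever cells were thinned.

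Genes named in the text came from a fixed rule. It allowed the 5 largest classes per isolation, but fewer reached 50 cells in both libraries, and cluster 1 was added later. Among genes with at least 30 UMIs, the rule took the 3 highest and 3 lowest ratios by interval bound. It also took 9 genes of prior interest such as Dmd, Utrn, Apoe, Cdkn1a and Mdm2, and the 3 most abundant members of each list. Because single cells held most UMIs of several of these genes, 5 highest and 5 lowest genes ranked without the highest cell were added later. The 19 gene lists were summarised by the median log2 ratio of members with at least 20 UMIs (pseudocount 0.5 UMI, at least 5 members), set against 10000 random lists drawn from the 50 genes on each side in expression. A list outside the middle 95% of random lists was called higher or lower, as a description of these libraries only. Of 143 pairs of list and class 69 lay outside. The random range was left upward by NF-kB and acute inflammation in 9 of 9 classes, interferon response in 6 of 8, extracellular matrix in 5 of 9 (downward in 2), cholesterol synthesis in 4 of 8, cell cycle, immediate early, satellite cell quiescence and unfolded protein response in 3 of 9 each (downward in 3, 5, 1 and 0), MHC class I and NRF2 in 2 of 9 (downward in 0 and 1), and differentiation in 2 of 8 (downward in 4). Free fibre RNA left it upward in 1 of 8 and downward in 5, p53 targets and oxidative phosphorylation downward in 2 of 9, MHC class II downward in 1 of 4, and dystrophin complex and lipoprotein uptake in 0. The haemoglobin list never reached 5 measured members, and mitochondrially encoded genes were used as a share of UMIs only.

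The ratio and list steps were tested on simulated data with counting noise alone, built on bulk FAP-like cells. Ratios fell on the right side of 1 in 49, 45, 50 and 50 of 50 genes planted at 2, 0.5, 4 and 0.25 times, and intervals held the true value in 92% to 98% of planted and 95.6% of 11973 unchanged genes. A p53 list planted 1.5 times higher came back at 0.57, and 0 of 15 other lists left the random range. The simulation held no variation between cells, so it says nothing of animals.

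Alternatives covered a stricter filter (500 genes, 10% mitochondrial UMIs), all barcodes, called doublets kept, Leiden resolutions 0.5 and 2.0, 15 principal components, naming by each cell's marker score, scaling by the median ratio, means over cells, thinning, list members with at least 10 or 100 UMIs, and mean in place of median. Leaving out the highest-scoring 5% of cells, counting cluster 1 as FAP-like, leaving out the highest cell of a gene, the alternatives for Cas9 levels and the minimum of 20 UMIs for a gene ratio under an alternative were added after results had been seen. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.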

Results

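The question in the series title is which cell types of skeletal muscle receive LNP-CRISPR. These are lipid nanoparticles (LNP) that deliver CRISPR, a gene-cutting system whose cutting enzyme is Cas9. Cas9 was counted here as RNA. Mice of a model of Duchenne muscular dystrophy (DMD), a disease of the Dmd gene for the muscle protein dystrophin, were given LNP-CRISPR or vehicle. Muscle cells were then sequenced singly, either as a bulk preparation or after a satellite cell isolation kit, and satellite cells are the stem cells of muscle. There was 1 library per group: vehicle bulk (1305 barcodes, 33801488 UMIs), LNP-CRISPR bulk (1317, 25921795), vehicle kit (1683, 28597422) and LNP-CRISPR kit (2207, 40666916). A UMI (unique molecular identifier) stands for 1 counted RNA molecule. After filtering, 1199, 1149, 1404 and 1899 cells remained, with medians of 22270, 16042, 8627 and 10312 UMIs per cell. Values are UMIs per 1000000 nuclear-encoded UMIs (CPM) summed over the cells of a class, and ratios are LNP-CRISPR over vehicle with 95% intervals in brackets. These intervals cover counting error only, and without replicate libraries no difference here can be assigned to the treatment rather than to the animals or preparations.

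Several genes of the text have these places on GRCm38 (mm10): Cxcl1 (chromosome 5, 90891241 to 90893115), Cxcl2 (chromosome 5, 90903871 to 90905938), Ccl2 (chromosome 11, 82035571 to 82037453), Nfkbia (chromosome 12, 55489410 to 55492647), Saa3 (chromosome 7, 46711998 to 46715700), Pax7 (chromosome 4, 139737062 to 139833528), Utrn (chromosome 10, 12382188 to 12869365) and Dmd (chromosome X, 82948870 to 85206141). Cas9 was counted on a sequence added to the mouse reference. Male-specific Ddx3y gave 3840, 2868, 1758 and 3139 UMIs in the 4 libraries, against 7, 2, 4 and 10 UMIs of Xist, which marks female cells.

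Cas9 RNA bears on the title's question only for barcodes that passed the isolation and the filter. It was absent from both vehicle libraries (0 UMIs). Among bulk LNP-CRISPR cells it was highest in cells resembling fibro-adipogenic progenitors (FAPs, matrix-making stromal cells) at 1986 CPM (1956–2017), followed by macrophage- or monocyte-like cells at 1488 CPM (1443–1533) and tenocyte-like cells, the cells of tendon, at 784 CPM (749–820). Neutrophil-like cells held 591 CPM (520–670), pericyte- or smooth muscle-like cells 249 CPM (205–301), dendritic-like cells 200 CPM (172–232), satellite-like cells 72.2 CPM (59.0–87.4), T or NK-like cells 55.2 CPM (32.7–87.3) and glial-like cells, the support cells of nerve, 19.3 CPM (3.99–56.5). Cluster 1, unnamed but rich in FAP markers, held 1213 CPM (1187–1239), and classes with fewer than 20 cells are not given. FAP-like cells thus held 27.5 (22.7–33.7) times the satellite-like level per UMI, an interval that leaves out how unevenly Cas9 lay between cells. The order of FAP-like over macrophage-like cells turned when each cell weighed the same (2318 against 3023 CPM), and naming each cell by its own marker score lowered macrophage-like cells to 537 CPM. A single macrophage-like cell held 1573 of the 4193 Cas9 UMIs of that class, and without it the level was 933 CPM. The order of the lower classes was not stable either: bulk pericyte-like cells ran from 92.8 CPM with a stricter filter to 717 CPM by marker score, dendritic-like cells came to 111 CPM and T or NK-like cells to 26.8 CPM without their highest cell, T or NK-like cells to 112 CPM by marker score, and with equal weights dendritic-like, neutrophil-like, satellite-like and glial-like cells came to 518, 966, 112 and 138 CPM.

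Counted per cell, at least 4 Cas9 UMIs were found in 71.5% (65.5–76.9) of FAP-like, 45.3% (35.6–55.3) of tenocyte-like, 41.9% (34.8–49.4) of macrophage-like, 18.9% (7.96–35.2) of bulk satellite-like, 10.9% (4.11–22.3) of dendritic-like and 8.33% (4.51–13.8) of neutrophil-like cells, but in 0% (0–15.4) of glial-like cells. At least 1 Cas9 UMI was present in 91.0% of FAP-like, 85.9% of tenocyte-like, 72.0% of macrophage-like and 70.3% of bulk satellite-like cells, and in 13.6% of glial-like cells, whose share is the nearest measure of free RNA, that is RNA from broken cells in the fluid of the droplets. Depth differed, with medians of 26287 UMIs in FAP-like, 24201 in satellite-like, 14876 in macrophage-like, 8549 in glial-like and 2556 in neutrophil-like cells. Thinned to 1000 UMIs per cell, 43.8% of FAP-like, 35.9% of tenocyte-like, 31.6% of macrophage-like, 19.8% of neutrophil-like, 13.9% of satellite-like and 0% of glial-like cells kept a Cas9 UMI. Cells with fewer UMIs were left out of these shares, among them 35 of 156 neutrophil-like and 9 of 186 macrophage-like cells. Within FAP-like cells, Cas9 was uneven between clusters, at 2526 CPM in cluster 4 and 2820 CPM in cluster 5 but 885 CPM in cluster 11 and 181 CPM in cluster 14. Macrophage-like cluster 3 held 1906 CPM and monocyte-like cluster 18 held 387 CPM, but 1 cell held 1573 of the 3893 Cas9 UMIs of cluster 3. At least 4 UMIs were found in 51.6% of the cells of cluster 3 and 21.7% of those of cluster 18.

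In the kit library the satellite-like cells held 263 CPM (257–269) of Cas9, 11.5 (9.10–14.7) times the glial-like level of 22.9 CPM (17.9–28.8). With called doublets kept, the glial-like level was 82.2 CPM, which makes that ratio far smaller. Tenocyte-like cells were highest at 915 CPM (846–989), or 554 CPM with the stricter filter, while pericyte- or smooth muscle-like cells held 97.0 CPM (89.0–106) and fibre-like barcodes, which carry transcripts of the contractile muscle fibre, 56.3 CPM (42.5–73.1). Per barcode, however, fibre-like barcodes held 0.194 Cas9 UMIs (0.147–0.253) and glial-like cells 0.166 (0.130–0.209), at median depths of 1652 and 7700 UMIs. At least 4 UMIs were found in 0.69% of fibre-like barcodes and 0.70% of glial-like cells. The higher fibre-like CPM therefore cannot be told apart from free RNA in barcodes of low depth. Satellite-like Cas9 lay in few cells: 15.7% (12.9–18.9) had at least 4 UMIs, the median cell had 0, the highest had 642, and the richest 10% of cells held 94.1% of it. At least 1 UMI was found in 39.3% of satellite-like, 39.1% of pericyte-like and 11.5% of glial-like cells, at medians of 26682, 18518 and 7700 UMIs. After thinning to 1000 UMIs these shares were 9.37% (7.15–12), 7.46% and 2.29% (1.05–4.30), with 28 of 363 pericyte-like and 35 of 428 glial-like cells left out for lower depth. Satellite-like clusters 23 (histone genes), 12 (Cdc20, Cenpf) and 22 (Myh3, Myog) held 400, 286 and 159 CPM, against 91.0 CPM in the Pax7 and Myf5 cluster 15 and 89.6 CPM in cluster 25. In cluster 12, 10 cells held 97.7% of it, and by cells with at least 4 UMIs the shares were 23.8% (17.3–31.5), 12.3% (6.08–21.5), 21.7% (13.4–32.1), 10.4% (6.86–14.99) and 11.6% (3.89–25.1) in the same order. Median depths over all libraries were 64900, 69049, 77977, 13592 and 21674 UMIs in that order, so these shares were not taken at equal depth. Cas9 RNA shows neither Cas9 protein nor edited Dmd DNA.

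**Figure D1:**
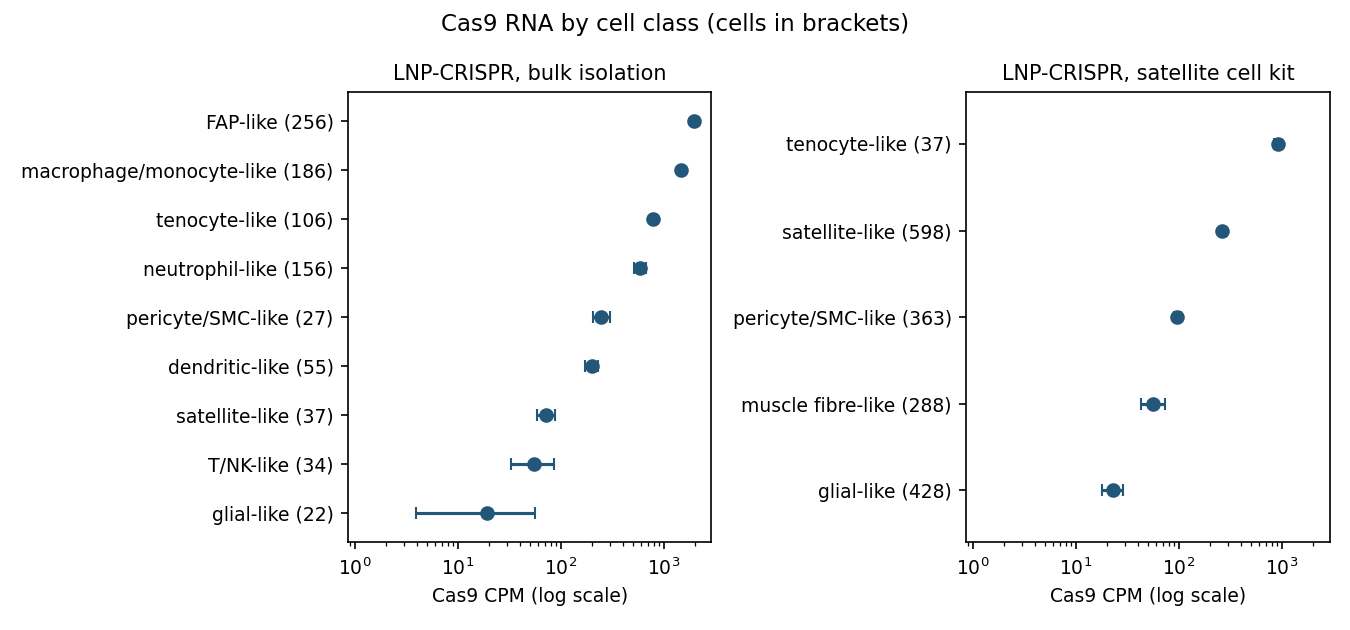
Cas9 per class in the LNP-CRISPR libraries, from 1986 CPM in bulk FAP-like cells to 19.3 CPM in bulk glial-like cells. Vehicle libraries held 0 Cas9 UMIs.

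The isolation labels ask what the kit enriches, and satellite-like cells were 37.3% (34.8–39.9) of vehicle kit cells, 10.4 (7.62–14.6) times their bulk share. In the LNP-CRISPR pair the same ratio was 9.78 (7.01–14). The class is wider than stem cells with Pax7, which was an enriched marker of cluster 15 only (237 of 524 vehicle kit cells). Clusters 12 and 23 were led by cell cycle and histone genes, and clusters 22 and 25 were enriched in Myog. Cluster 15 alone was 16.9% of vehicle kit and 1.92% of vehicle bulk cells. Other cells came along: glial-like shares were 11.3 (7.10–19.1) and 11.8 (7.67–19.0) times higher with the kit, fibre-like shares 17.0 (9.97–31.5) and 9.68 (6.02–16.6) times, and pericyte- or smooth muscle-like shares 5.50 (3.66–8.59) and 8.14 (5.50–12.5) times. Tenocyte-like cells were depleted to 0.211 of the bulk share in both pairs, FAP-like cells to 0.00195 and 0.0118, and macrophage-like cells to 0.00813 and 0.00976. With 43 and 37 satellite-like cells in bulk, their expression was not compared between isolations.

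The treatment labels ask how muscle after LNP-CRISPR differs from muscle after vehicle, and in bulk the clearest difference in cell types was in neutrophil-like cells, blood-borne first responders, at 13.6% (11.7–15.7) of LNP-CRISPR cells against 2.75% (1.90–3.84) of vehicle cells. That is a ratio of 4.93 (3.37–7.42). FAP-like cells were lower, at 22.3% (19.9–24.8) against 36.5% (33.8–39.3), a ratio of 0.610 (0.521–0.713). Leaving neutrophil-like cells out of the total gave 25.8% against 37.6%, and naming each cell by its own marker score gave 37.9% against 54.4%. Tenocyte-like cells were 9.23% against 6.76%, with a ratio of 1.37 (1.01–1.85). Macrophage-like cells (16.2% against 17.5%, ratio 0.924, 0.755–1.13), dendritic-like cells (1.04, 0.705–1.55), T or NK-like cells (1.61, 0.916–2.89) and bulk satellite-like cells (0.898, 0.563–1.43) had intervals that included 1. Unnamed cells were 21.2% with LNP-CRISPR and 21% with vehicle, among them 24 LNP-CRISPR cells (2.09%) with neutrophil markers but a stromal leading gene. Shares within a library are tied to each other, so a higher neutrophil-like share lowers the rest.

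In the kit libraries pericyte- or smooth muscle-like cells were 19.1% with LNP-CRISPR and 12.4% with vehicle, a ratio of 1.54 (1.28–1.86). With the stricter filter these shares were 15.98% and 7.63%. Glial-like cells were 22.5% against 18% (ratio 1.26, 1.07–1.47). Satellite-like cells were 31.5% (29.4–33.6) against 37.3% (ratio 0.844, 0.749–0.951), and fibre-like barcodes 15.2% against 19.9% (ratio 0.763, 0.645–0.903). The largest group of vehicle pericyte-like cells was cluster 9 (85 of 174) and that of LNP-CRISPR ones cluster 6 (205 of 363), so this class did not hold the same mixture in both libraries.

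**Figure D2:**
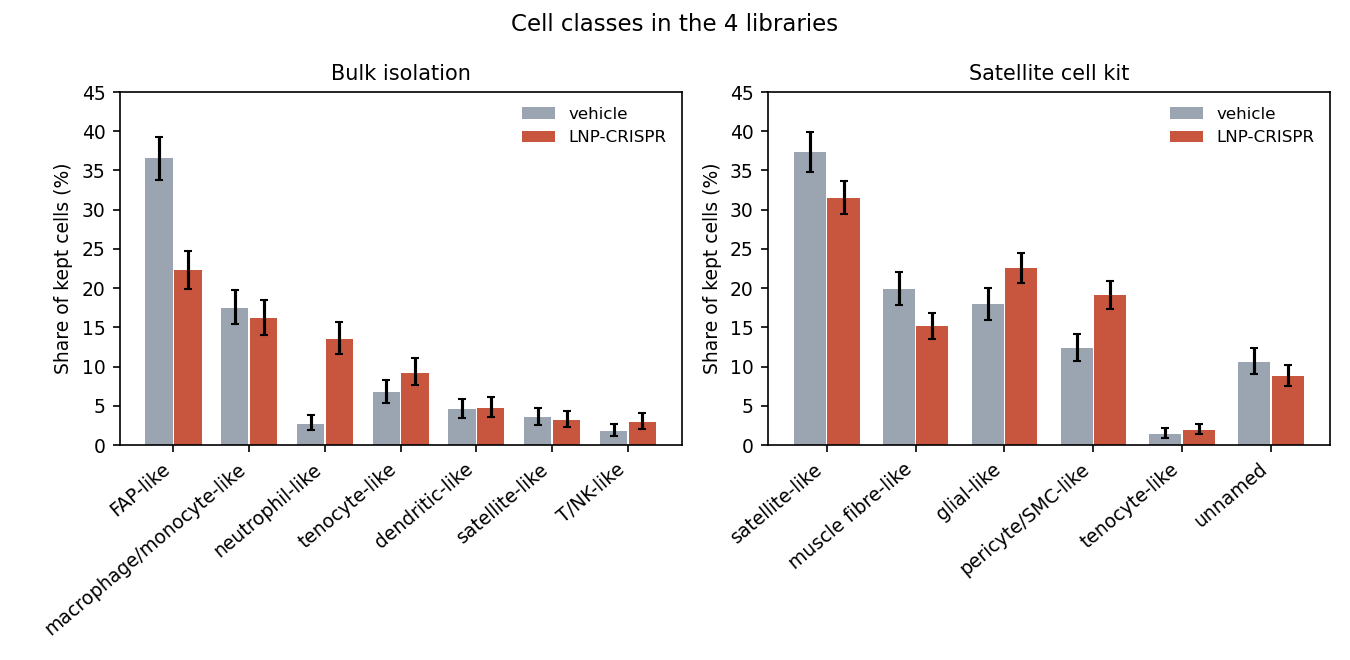
Class shares per library. Neutrophil-like cells were 2.75% of vehicle bulk and 13.6% of LNP-CRISPR bulk cells.

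Bulk FAP-like cells (438 vehicle, 256 LNP-CRISPR), the class with the most Cas9 CPM summed over cells, had higher acute inflammatory RNA after LNP-CRISPR. The fixed list of NF-kB and acute inflammation genes, which are switched on by the transcription factor NF-kB, had a median log2 ratio of 1.01, with 27 of 28 members higher. Ccl2, which attracts monocytes, had a ratio of 2.48 (2.43–2.53), Cxcl1, which attracts neutrophils, 1.97 (1.94–2.01), and Nfkbia, which encodes an inhibitor of NF-kB, 1.52 (1.48–1.56). The interferon-induced chemokine Cxcl10 was 5.85 (5.55–6.17) times higher, at 799 against 137 CPM, and Rnd1, a small GTPase of the cytoskeleton, was 7.80 (6.93–8.79) times higher, at 203 against 26.1 CPM. Among the genes with the highest ratios were the acute-phase gene Saa3 (15.3, 13.7–17.1) and the growth factor gene Csf2 (28.4, 19.8–42.2), beside the chemokine Ccl20 (22.5, 15.3–34.2). Csf2 was seen in 7 vehicle and 18 LNP-CRISPR cells and Ccl20 in 4 and 10, and with called doublets kept Csf2 came to 65.3. Csf3, seen in 4 and 7 cells, was at 3.40 (2.51–4.66), but 1 cell held 60 of its 63 vehicle UMIs, and without the highest cells it was at 29.3 (9.50–146). Saa3 leads the markers of cluster 4 (305 of 438 vehicle and 170 of 256 LNP-CRISPR cells), and Ccl20, Csf2 and Ccl2 those of cluster 11 (48 and 33 cells).

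Lower in FAP-like cells were Inmt, a methyltransferase gene (0.198, 0.135–0.282), the adhesion gene Cadm1 (0.113, 0.0355–0.275), the stress hormone gene Gdf15 (0.271, 0.152–0.456, or 0.641 with called doublets kept) and Apoe, whose protein carries lipid (0.528, 0.482–0.578). Spp1, for the matrix protein osteopontin, had a ratio of 0.0968 (0.0849–0.110), but 2477 of its 4052 vehicle UMIs were in 1 cell, and the ratio was 0.196 without the highest cell and 0.469 with equal weights per cell. Gpr183 and Atp6v0d2 also rested on few cells, with 49 of 52 vehicle Gpr183 UMIs in 1 of them. The p53 target list, genes switched on after DNA damage, was lower at −0.22, with 21 of 29 members lower, but it lay inside the random range with called doublets kept (−0.078), the stricter filter (−0.16), Leiden resolution 2.0 (−0.13) or the highest cells left out (−0.20). Its members included Btg2 (0.898, 0.856–0.942) and Mdm2 (0.775, 0.684–0.877), whereas Cdkn1a, which stops the cell cycle, was at 1.05 (0.970–1.14). Mdm2 turned to 1.13 without its highest cell and to 1.02 with called doublets kept. Immediate early genes, which respond within minutes to cell handling, were slightly lower (−0.14, 18 of 25 members lower, but −0.025 and inside the random range at Leiden resolution 2.0), with Jun at 0.851 (0.836–0.867) and Fos at 0.824 (0.806–0.842). The interferon response list as a whole stayed inside the random range (−0.06, 20 of 41 members higher) in spite of Cxcl10, with Ifitm3 at 1.04 and Ly6e at 0.855.

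Macrophage- or monocyte-like cells (210 vehicle, 186 LNP-CRISPR) had a smaller NF-kB difference, with a median of 0.20 and 18 of 29 members higher. Cxcl2, another neutrophil attractant, had a ratio of 1.58 (1.54–1.62) and Ccl2 1.15 (1.08–1.22), while Nfkbia was level at 0.994 (0.940–1.05). Serpinb2, a protease inhibitor gene (4.42, 3.57–5.52, or 6.73 after thinning), the elastase gene Mmp12 (4.17, 3.27–5.37) and the lysozyme gene Lyz1 (8.78, 6.68–11.7, or 5.29 without its highest cell) were higher. The anti-inflammatory cytokine gene Il10 (0.221, 0.129–0.360), the lectin gene Mgl2 (0.178, 0.0728–0.381), the chemokine gene Ccl8 (0.309, 0.217–0.432) and the heat shock genes Hspa1a (0.314, 0.271–0.364) and Hspa1b (0.271, 0.228–0.320, or 0.406 after thinning) were lower. The interferon list was higher (0.30, 28 of 41 members) and p53 targets were lower (−0.34, 18 of 24 members, but −0.12 and inside the random range over members with at least 100 UMIs), with Gdf15 at 0.699 and Cdkn1a at 1.10, the latter 0.978 (0.731–1.30) after thinning. Neutrophil RNA was more abundant here, as S100a8 and S100a9 together made 289 against 188 CPM, and S100a9 turned from 0.727 to 5.70 without its highest cell. Cxcl9 (0.0373) likewise came to 0.951 without its highest cell, and UMIs of the mast cell protease genes Mcpt4, Cma1 and Tpsb2 came from 1 or 2 LNP-CRISPR cells.

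Tenocyte-like cells (81 vehicle, 106 LNP-CRISPR) had an NF-kB median of 1.12, with 23 of 24 members higher. Ccl2 had a ratio of 4.35 (3.84–4.92), Nfkbia 2.57 (2.37–2.79) and Cxcl2 12 (6.67–23.6). Higher too were Il1rl1, the receptor gene for interleukin 33 (14.3, 8.33–26.5, but 32.9 with the stricter filter and 8.26 with equal weights), Rnd1 (11.3, 5.77–25.4), Igfbp2, which binds insulin-like growth factors (10.5, 5.84–20.8), and the protease inhibitor gene Slpi (2.75, 2.30–3.31). Ptx3, an innate immune protein gene, was at 9.91 (6.63–15.4), or 2.70 without its highest cell, and Cxcl2, Igfbp2, Rnd1 and Slpi came to 7.11, 28.0, 74.7 and 9.89 without theirs. Interferon genes were higher (0.57, 26 of 31 members), among them Ly6e at 1.73 and Ifit1 at 3.39, the latter seen in 2 vehicle and 8 LNP-CRISPR cells and at 49.96 (13.5–418) without its highest cell. Ccn3, a secreted matrix-associated protein gene (0.267, 0.175–0.397), and the receptor gene Uts2r (0.284, 0.198–0.40) were lower, as were Nudt18 (0.221) and Arhgap20 (0.247), while Mmp13, Ccl5 and Tac1 were lower but lay in at most 6 cells per library. S100a8 and S100a9 made 71.8 against 12.3 CPM here, and 50.6 against 11.8 CPM in FAP-like cells.

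Dendritic-like cells (55 in each library) had an NF-kB median of 0.29, with 17 of 23 members higher, Cxcl2 at 2.34 (2.18–2.51) and the interleukin gene Il1b at 1.33. Cdkn1a was 1.64 (1.41–1.92) times higher, or 2.70 times after thinning, and the lectin gene Clec10a (0.358, 0.286–0.445, or 0.230 with equal weights) and Fos (0.511) were lower. Immediate early genes were lower (−0.40, 19 of 24 members). Ccl5 (44.8, 20.2–123), a T cell attractant gene, was found in 9 LNP-CRISPR cells, and Fscn1, an actin-bundling protein gene of mature dendritic cells, in 5. The interferon list was higher at 0.35 but came to −0.02 over members with at least 100 UMIs. Apoe (19.2, 13.8–27.6) and the stromal gene Mgp (14.1) were higher, though Apoe came to 3.09 after thinning and Mgp to 3.32 with called doublets kept. S100a8 and S100a9 were higher too (215 against 28.8 CPM). RNA of other cell types may thus be part of this comparison.

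Cluster 1 (223 vehicle, 174 LNP-CRISPR), which had 30 FAP markers but stayed unnamed because its 10 leading genes held 1 marker of another class and 0 of FAPs, had NF-kB genes higher by 0.62 (27 of 28 members) and interferon genes higher by 0.53 (38 of 41 members). Saa3 (45.2, 15–223, or 27.6 with equal weights), Slpi (33.9, 14.1–106, or 13.4 with equal weights), Cxcl10 (5.42, 5.02–5.87) and Cxcl1 (1.36) were higher, and Areg, a growth factor gene of repair (0.144, or 0.0723 without its highest cell), and Plk2 (0.540) were lower. Its immediate early genes were higher (0.23, 19 of 25 members), unlike those of the other bulk classes.

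Kit satellite-like cells (524 vehicle, 598 LNP-CRISPR) also had higher NF-kB RNA, with a median of 0.73 and 22 of 23 members higher. Since UMIs were summed over cells, clusters of greater depth weighed more in every value of this class. In vehicle kit, the Pax7 and Myf5 cluster 15 gave 3173567 of 19431948 nuclear-encoded UMIs. Clusters 12 and 23, led by cell cycle and histone genes, gave 5930482 and 6211135. The values are therefore not those of resting stem cells alone. Cxcl2 had a ratio of 6.17 (5.74–6.64), Cxcl3 5.35 (4.43–6.50), Cxcl1 2.5 (2.43–2.57), Nfkbia 1.95 (1.90–2.0), and the monocyte and T cell attractants Ccl7 and Ccl5 8.09 (6.01–11.1) and 13.6 (7.61–26.7). With equal weights per cell Cxcl3 came to 3.08 and Ccl7 to 5.05, and Ccl5 came to 7.51 without its highest cell. The interferon list was higher by 0.17 (22 of 33 members), with the transcription factor gene Irf1 at 1.68 (1.53–1.84). Quiescence genes, which mark resting stem cells, were lower (−0.20, 21 of 24 members), including Pax7, the stem cell transcription factor gene, at 0.913 (0.846–0.985), Apoe at 0.700 (0.654–0.750) and Fos at 0.678. The mixture of clusters differed here too, as the Pax7 and Myf5 cluster 15 made 237 of 524 vehicle and 240 of 598 LNP-CRISPR cells and the Myog cluster 22 made 48 and 83, so the lists of quiescence and differentiation also reflect that mixture. Klf2, a transcription factor gene of the immediate early list, was at 0.445 (0.404–0.490), and that list was lower by 0.32 (21 of 25 members). The differentiation list was higher by 0.22 (19 of 26 members), with Tnnc1, for a troponin of the contractile machinery, at 3.80 (3.32–4.36), Acta1 at 1.36 (1.33–1.39), Myod1 at 1.07 (1.02–1.11) and Myog, for a factor that starts differentiation, at 1.09 (1.07–1.12). With finer clusters (Leiden resolution 2.0) that list came to −0.12, Myog to 0.930 and Myod1 to 1.03 (0.989–1.08), and with cells thinned to 1000 UMIs Pax7 came to 1.09 (0.764–1.56), Myog to 0.869 (0.721–1.05) and Myod1 to 1.09 (0.820–1.45). Lower were the iron exporter gene Slc40a1 (0.334), the clock-controlled factor gene Hlf (0.251) and Slamf1 (0.269), while Sln rested on 1 cell, turning from 0.180 to 1.20 without it.

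Kit glial-like cells (252 vehicle, 428 LNP-CRISPR), which held little Cas9, had an NF-kB median of 1.04, with 14 of 16 members higher. Cxcl2 was at 17.3 (7.26–53.8), Cxcl1 at 8.06 (4.95–14), Cxcl10 at 2.72 (2.06–3.64), Nfkbia at 1.81 (1.65–1.98), and Thbs1, for the matrix protein thrombospondin, at 14.1 (6.37–39.1). With equal weights per cell, Cxcl2 came to 3.18, Thbs1 to 4.09 and Cxcl10 to 1.19. Interferon genes were higher by 0.30 (16 of 21 members), or by 0.21 and inside the random range as a mean over members, with Irf1 at 1.45. Free fibre RNA was lower in the LNP-CRISPR glial-like cells, with Tnnt3 at 0.434 (0.379–0.496) and Acta1 at 0.530.

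Kit pericyte- or smooth muscle-like cells (174 vehicle, 363 LNP-CRISPR) had an NF-kB median of 0.51 (16 of 21 members higher), with Cxcl2 at 14.4 (10.2–20.9), Cxcl1 at 2.65 (2.52–2.79) and Nfkbia at 1.70 (1.63–1.78). The cytokine gene Lif was at 5.18 (2.72–11.1), the peptide transporter gene Slc15a2 at 4.07 (2.71–6.36), Cdkn1a at 1.47 (1.38–1.56) and Mdm2 at 1.53 (1.16–2.04), with Cdkn1a at 1.13 after thinning, while the p53 list as a whole stayed inside the random range. S100a4 (0.325, or 0.467 after thinning) and the deubiquitinase gene Otud1 (0.25) were lower, and Rffl (12.8, 3.40–109) and Cited1 (14.4, 3.83–122) were higher. The stricter filter moved Cxcl2 to 62.7, Lif to 31.3 and Slc15a2 to 2.68, and leaving out the highest cell moved Lif to 14.4, Rffl to 23.6 and Cited1 to a lower bound of 3.82. The cluster mixture of this class differed between the libraries, which limits all of these values.

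Kit fibre-like barcodes (279 vehicle, 288 LNP-CRISPR) had an NF-kB median of 1.89 over 9 measured members, with Nfkbia at 3.74 (2.39–5.99) and Tnfaip2 at 3.16 (2.28–4.44). In this class all genes had a median of 0.20 when scaled by total UMIs. Lists more typical of other cell types were higher as well. Satellite cell quiescence genes were at 0.97 (7 of 8 members, a call lost without the highest cells), matrix genes at 0.83 (10 of 11) and cell cycle genes at 0.79 (14 of 14). RNA of other cells may thus be part of this comparison, which was not tested. Egr1, an immediate early gene, was at 5.88 (4.68–7.45), Ttn, for the giant sarcomere protein titin, at 3.91 (3.73–4.11), and the transcription factor gene Runx1 at 13.6 (6.86–30.7), seen in 6 vehicle and 21 LNP-CRISPR barcodes. With equal weights per barcode, Egr1 came to 1.45, Ttn to 1.76 and Runx1 to 7.83. Acta1 (0.798) and Ckm (0.833), for actin and creatine kinase of the fibre, were lower, as were Map3k7cl (0.247) and Rgcc (0.401), which came to 0.463 and 0.894 with equal weights. Mitochondrial UMIs were 1.82% against 1.37% in these barcodes.

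**Figure D3:**
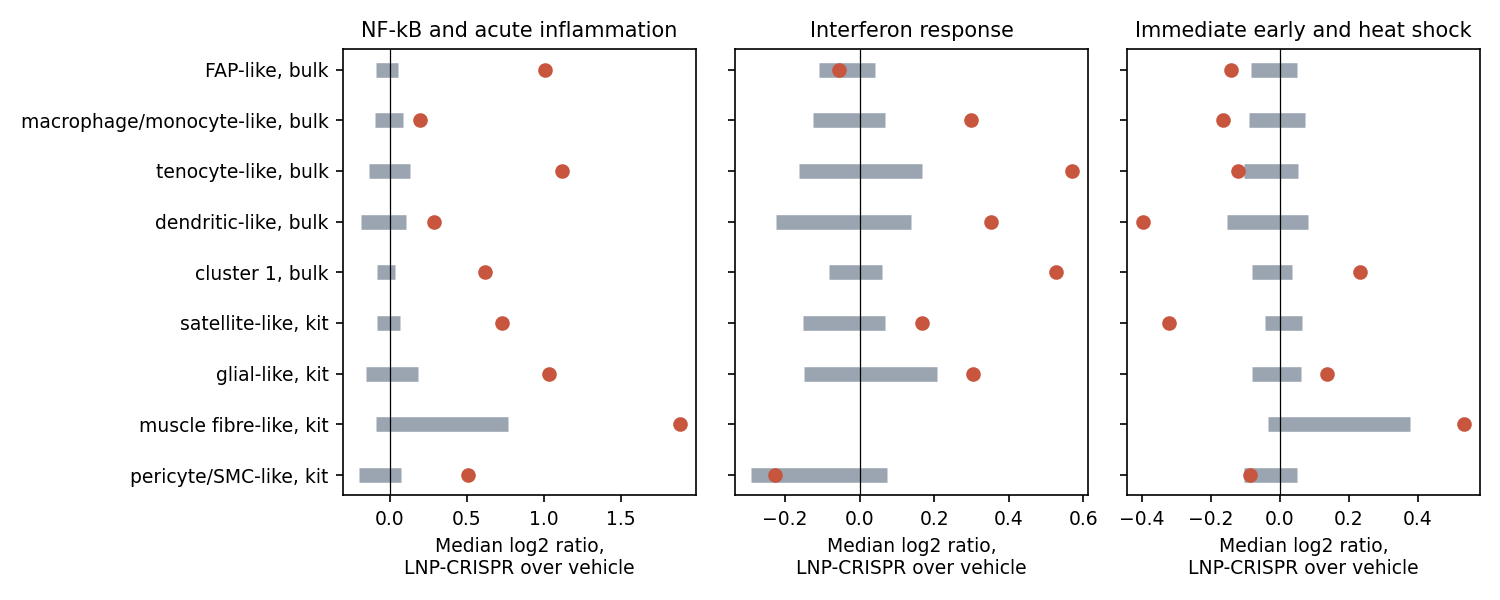
Median log2 ratio per class of the NF-kB and acute inflammation, interferon response, and immediate early and heat shock lists. The NF-kB list ran from 0.20 in macrophage-like to 1.89 in fibre-like cells.

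Dmd, the dystrophin gene of the disease, was level in FAP-like cells at 1.0 (0.796–1.26) and glial-like cells at 0.995, and was 0.738 (0.456–1.19) in tenocyte-like cells. In satellite-like cells it was 0.799 (0.708–0.902), at 21.6 against 27.1 CPM, and 1.08 (0.686–1.71) when cells were thinned to 1000 UMIs, an interval that also holds the value before thinning. In fibre-like barcodes its ratio of 4.79 (2.91–8.19) came from 8 LNP-CRISPR and 7 vehicle barcodes. Utrn, for the dystrophin relative utrophin, was at 0.946 (0.865–1.03) in FAP-like, 1.02 (0.959–1.09) in satellite-like and 1.14 (1.09–1.20) in glial-like cells, and its ratio of 2.46 (1.37–4.57) in fibre-like barcodes came to 0.696 when each barcode weighed the same. The dystrophin complex list stayed inside the random range in 8 of 8 classes, and the list of lipoprotein receptors and particle uptake genes in 9 of 9. The p53 list was outside the random range in 2 of 9 classes, lower in both, and neither call held under every alternative. Counts at the ends of transcripts tell nothing of edits within Dmd.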

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

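In the patterns below, the tests of free RNA in satellite-like cells, of macrophage-like shares, of blood without Hba-a2, of dissociation and of animals were chosen only after their result had been seen. The others were written down once the pattern was known but before their values were computed.

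Barcodes left out for a mitochondrial share above 20%, often a mark of damaged cells, held more Cas9 per UMI than the cells kept. In LNP-CRISPR bulk 161 such barcodes held 10780 Cas9 UMIs per 1000000 UMIs against 1237 in kept cells, and in the LNP-CRISPR kit library 300 held 1015 against 212. Their depth was lower, with medians of 2293 against 16042 UMIs in bulk and 5539 against 10312 in the kit library. Per barcode the gap was small in bulk, at 29.95 Cas9 UMIs in all barcodes not kept against 27.3 in kept cells, and 7.14 against 4.29 in the kit library. Vehicle barcodes of this kind held 0. The class levels of Cas9 therefore describe cells that passed the filter, and Cas9 in the others was not assigned to cell types.

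Cas9 lay in a minority of satellite-like cells of the kit library. Free Cas9 RNA that followed each cell's depth would give a variance of 9.68 times the mean, and the variance was 247 times the mean. Doublets with stromal cells are argued against by FAP and tenocyte marker RNA, which was lower in the 94 cells with at least 4 Cas9 UMIs than in the other 504 (ratio 0.695, 0.671–0.720). Greater depth of the Cas9-holding cells (median 45450 against 24520 UMIs) is not enough, as after thinning the richest 10% of cells held 100% of 139 Cas9 UMIs where equal chance gives 53.8%. Doublets with other cell types stay open, since Scrublet called few.

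Neutrophil-like cells were a larger share of LNP-CRISPR bulk. More barcodes of low depth was tested by the ratio among barcodes with at least 2000 UMIs. It was 6.29 (3.67–11.5), so the higher share did not rest on barcodes under that limit alone. But median depths of neutrophil-like cells were 1637 UMIs in vehicle and 2556 in LNP-CRISPR bulk, so the limit removed a larger part of the vehicle ones. Whether shallow neutrophils were called as cells less often in the vehicle library stays open. More blood was first tested by all haemoglobin RNA, whose ratio of 20.6 (16.4–26.2) came almost wholly from Hba-a2, which proved a poor measure of blood here because the other haemoglobin genes did not follow it. Those others gave 1.33 (0.936–1.89) on 67 and 68 UMIs, and monocyte-like cluster 18 gave 1.03 (0.707–1.49). A loss of the other types cannot be told apart from a gain of neutrophils, since both put the other shares near 0.889 times the vehicle value, and the macrophage-like ratio was 0.924 (0.755–1.13).

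NF-kB and acute inflammation RNA was higher in all 9 compared groups. Free RNA from neutrophils could account for at most 2.01% of the excess in any bulk class. Free RNA from other cell types was not tested, nor was any free RNA in the kit classes. FAP-like cells, for example, held 18040 CPM of this list with LNP-CRISPR, against 7645 CPM in dendritic-like cells. For a stronger dissociation response, the immediate early list was read, at −0.12 or lower in FAP-, tenocyte-, macrophage-, dendritic- and satellite-like cells. That call was lost in FAP-like cells at Leiden resolution 2.0 (−0.025) and in tenocyte-like cells without the highest cells (−0.073). In cluster 1 and in glial-, fibre- and pericyte-like cells the list was higher or inside the random range (lowest −0.088). The classes were split only after these values were seen, and genes that respond within minutes need not follow longer handling. A dissociation response therefore cannot be told apart from a treatment response in any class. With 1 library per group, a difference between animals or preparations cannot be told apart from the treatment either.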

How the results depend on the processing

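No paired analysis was possible because the labels do not link libraries by animal and there was 1 library per group. The cause was not tested for any value below. NF-kB genes stayed above the random range in all 9 groups under every alternative run, the FAP-like share ratio stayed between 0.582 and 0.696, the neutrophil-like ratio between 4.58 and 5.69, and the kit satellite-like ratio between 0.801 and 0.899. Of alternatives run, 36 of 162 class shares, 2 of 98 Cas9 shares and 42 of 126 Cas9 levels moved. For lists 9 of 1077 reversed, 94 moved, 26 were stronger and 47 weaker, and for gene ratios 20 of 991 reversed, 30 moved, 5 were stronger and 24 weaker. A further 129 gene ratios had under 20 UMIs and no value, 12 of them in the other direction. Leaving out the highest-scoring 5% of cells, counting cluster 1, all alternatives for Cas9, leaving out the highest cell and that minimum were added after the data were seen. Shares are vehicle then LNP-CRISPR, Cas9 levels are CPM, lists are median log2 ratios, and each main value stands after "from" or elsewhere in the text.

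With the stricter filter (500 genes, 10% mitochondrial UMIs), shares were FAP-like 42.9% and 29.7%, kit satellite-like 45% and 38.5%, glial-like (LNP-CRISPR) 25.2%, pericyte-like 7.63% and 15.98%, and fibre-like 15.8% and 11.9%. FAP-like cells with at least 4 Cas9 UMIs were 64.9%, and Cas9 was 1685 in FAP-like, 1134 in macrophage-like, 103 in T or NK-like, 92.8 in bulk pericyte-like and 554 in kit tenocyte-like cells. Weaker lists were FAP-like p53 −0.16, MHC class II −0.52 (from −0.79), differentiation −0.23 (from −0.38) and cell cycle 0.007, fibre-like immediate early 0.41 (from 0.53) and pericyte-like differentiation −0.21 (from −0.82). Reversed were fibre-like Myl4 1.40 (from 0.326), Tnni1 1.14 (from 0.207) and differentiation 0.65 (from −0.26), and pericyte-like Myog 1.48 (from 0.190) and cholesterol −0.10 (from 0.07).

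With called doublets kept, FAP-like shares were 32.4% and 18.8%, Cas9 was 1605 in FAP-like and 82.2 in kit glial-like cells. FAP-like Mdm2 reversed to 1.02 and macrophage-like matrix to −0.75. FAP-like p53 was −0.078, macrophage-like cell cycle −0.21 and dendritic-like matrix 0.10.

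At Leiden resolution 0.5, FAP-like shares were 55.2% and 37.4%, kit pericyte-like 9.97% and 15.9%, and Cas9 was 1637 in FAP-like and 104 in T or NK-like cells. At 2.0, FAP-like shares were 43.7% and 29.1% and the LNP-CRISPR satellite-like share 28.9%, with Cas9 at 1803 in FAP-like and 269 in kit satellite-like cells. FAP-like p53 was −0.13, immediate early −0.025, differentiation −0.22 and cell cycle 0.024. Reversed were satellite-like Myog 0.930 and differentiation −0.12 and fibre-like differentiation 0.08.

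By marker score per cell, shares were FAP-like 54.4% and 37.9%, kit satellite-like 32.7% and 29.4%, and fibre-like 28.0% and 19.96%. FAP-like cells with at least 4 Cas9 UMIs were 64.6%, and Cas9 was 1607 in FAP-like, 828 in bulk tenocyte-like, 717 in bulk pericyte-like, 537 in macrophage-like, 267 in dendritic-like, 112 in T or NK-like and 192 in kit satellite-like cells. With cluster 1 counted, FAP-like shares were 55.1% and 37.4%.

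With all barcodes kept, shares were macrophage-like (LNP-CRISPR) 13.9%, glial-like (LNP-CRISPR kit) 20.2%, kit pericyte-like 15.3% and 22.5%, and fibre-like 17.0% and 13.4%. With 15 principal components kit pericyte-like shares were 10.0% and 16.1%, and Cas9 was 1727 in FAP-like and 106 in T or NK-like cells. With the highest-scoring 5% left out they were 10.1% and 16.6%, and Cas9 was 1826 in FAP-like, 242 in kit satellite-like and 637 in kit tenocyte-like cells.

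By the mean over each cell's own CPM, bulk Cas9 was 2318 in FAP-like, 3023 in macrophage-like, 966 in neutrophil-like, 518 in dendritic-like, 138 in glial-like and 112 in satellite-like cells, and kit Cas9 1238 in tenocyte-like, 81.1 in fibre-like and 34.2 in glial-like cells. Reversed were macrophage-like S100a9 1.77, cluster 1 Utrn 1.06 (from 0.880), fibre-like Utrn 0.696 and pericyte-like Myod1 2.98 (from 0.304).

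Without the cell with the most Cas9, bulk Cas9 was 1880 in FAP-like, 933 in macrophage-like, 576 in tenocyte-like, 470 in neutrophil-like, 111 in dendritic-like, 96.8 in pericyte-like, 52.1 in satellite-like and 26.8 in T or NK-like cells, and kit Cas9 654 in tenocyte-like and 239 in satellite-like cells.

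Without the highest cell of each gene, reversed were FAP-like Mdm2 1.13, macrophage-like S100a9 5.70, tenocyte-like differentiation −0.008 (from 0.55), satellite-like Sln 1.20, and fibre-like Myl4 1.22 and differentiation 0.43. Weaker were FAP-like p53 −0.20 and MHC class II −0.33, macrophage-like differentiation −0.10 (from −0.57), cell cycle −0.033 and free fibre RNA −0.31, tenocyte-like immediate early −0.073 (from −0.12), matrix −0.082 and free fibre RNA 0.25, glial-like oxidative phosphorylation −0.064, fibre-like quiescence 0.52 (from 0.97) and unfolded protein response 0.54 (from 0.56), and pericyte-like cholesterol 0.073.

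By the mean over members, lists were FAP-like MHC class II −0.65, differentiation −0.33 and cell cycle 0.064, macrophage-like unfolded protein response 0.06 (from 0.16), tenocyte-like matrix −0.068, dendritic-like MHC class I 0.22, cluster 1 quiescence 0.086 (from 0.09) and cell cycle 0.12, satellite-like oxidative phosphorylation −0.04, glial-like interferon 0.21, immediate early 0.054 (from 0.14), NRF2 0.12 and oxidative phosphorylation −0.056, and pericyte-like matrix 0.07. Fibre-like free fibre RNA reversed to 0.19 (from −0.12). With members of at least 10 UMIs, FAP-like differentiation was −0.38 and fibre-like free fibre RNA −0.088. With at least 100, macrophage-like p53 was −0.12 and cell cycle −0.11, dendritic-like interferon reversed to −0.021, dendritic-like MHC class I was 0.12, cluster 1 MHC class I 0.041 and pericyte-like cholesterol 0.074. Scaled by the median ratio, pericyte-like cholesterol was 0.16.

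Thinned to 1000 UMIs per cell, reversed were macrophage-like Cdkn1a 0.978 (0.731–1.30) and S100a9 2.84 (1.26–6.997), and satellite-like Cdkn1a 0.975 (0.759–1.25, from 1.15), Dmd 1.08 (0.686–1.71), Mdm2 0.922 (0.557–1.53, from 1.14), Myog 0.869 (0.721–1.05) and Pax7 1.09 (0.764–1.56). Few UMIs are left after thinning, and all of these intervals except that of S100a9 include 1.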

Other observations

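Beyond inflammation, RNA of the extracellular matrix, the scaffold around cells, was higher in LNP-CRISPR dendritic-like cells (0.69, 19 of 23 members), macrophage-like cells (0.22, 19 of 27), glial-like cells (0.17, 17 of 25), fibre-like barcodes (0.83, 10 of 11) and pericyte-like cells (0.10, 21 of 28). Dendritic-like cells also held more of the stromal gene Mgp (14.1, or 7.41 without its highest cell) and of Apoe (19.2, or 10.9), so stromal RNA may be part of their matrix value, which came to 0.10 with called doublets kept. In macrophage-like cells Thbs1 had a ratio of 1.24 and Fn1, for fibronectin, 1.22. It was lower in tenocyte-like cells (−0.12, 20 of 30 members lower), with the collagen gene Col1a1 at 0.901 and Sparc at 0.844, and in satellite-like cells (−0.13, 22 of 30), and level in FAP-like cells (0.01), with Col3a1 at 0.955. With called doublets kept, the matrix list turned to −0.75 in macrophage-like cells, and the tenocyte-like (−0.082 without the highest cells) and pericyte-like calls (0.07 as a mean over members) were also lost. Cell cycle genes were lower in dendritic-like (−0.53, 19 of 27 members lower) and macrophage-like cells (−0.23, 19 of 28), with Tubb5 at 0.577 and Hmgb2 at 0.613 in the former, and in satellite-like cells (−0.10, 19 of 32). They were slightly higher in FAP-like cells (0.08, 21 of 32) and cluster 1 (0.12, 20 of 29) and higher in fibre-like barcodes (0.79, 14 of 14). In these barcodes quiescence (0.97, a call lost without the highest cells) and matrix genes (0.83) and the median of all genes (0.20) were higher too. The cell cycle calls of macrophage-like cells (−0.033), FAP-like cells (0.007) and cluster 1 (0.115) were lost under at least 1 alternative. Cholesterol genes were higher in FAP-like cells (0.20, 14 of 20), with the regulator gene Srebf2 at 1.28 (1.13–1.44), in cluster 1 (0.21, 18 of 20) and in satellite-like cells (0.11, 15 of 20).

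NRF2 genes, which answer oxidative stress, were higher in macrophage-like cells (0.16, 12 of 14), including Hmox1 at 1.14 and Fth1, for iron storage, at 1.13, and in glial-like cells (0.25, a call lost as a mean over members), and lower in dendritic-like cells (−0.23, 10 of 13 lower). MHC class II genes, which present antigen, were lower in FAP-like cells (−0.79, 6 of 7), but the call was lost without the highest cells (−0.33), with the stricter filter (−0.52) and as a mean over members (−0.65). Of 141 vehicle Cd74 UMIs 49 were in 1 cell, and its ratio of 0.570 was 0.815 (0.561–1.17) without the highest cells. MHC class I genes were higher in dendritic-like cells (0.16) and cluster 1 (0.12), and nuclear genes of oxidative phosphorylation were slightly lower in satellite-like (−0.05, 28 of 35) and glial-like cells (−0.06), and these 4 calls were each lost under at least 1 alternative. Free fibre RNA was lower in FAP-like (−0.54, 15 of 15), macrophage-like (−1.02, 13 of 13), glial-like (−0.98, 16 of 18) and pericyte-like cells (−0.91, 18 of 18), and higher in tenocyte-like cells (0.84, 7 of 8), where macrophage-like cells (−0.31) and tenocyte-like cells (0.25) lost the call without the highest cells. Mitochondrial UMIs were 4.45% against 5.04% in satellite-like and 5.04% against 6.05% in glial-like cells, but 1.82% against 1.37% in fibre-like barcodes and 3.52% against 3.16% in cluster 1.

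As a hypothesis, written after Cas9 levels were known but before these values were computed, cells with more Cas9 may hold more response RNA, which was looked at within FAP-like cluster 4 of LNP-CRISPR bulk. The 56 cells richest in Cas9 (6828 CPM) were set against the 56 poorest (92.9 CPM) at similar depths of 26368 and 25556 UMIs. NF-kB genes were higher by 1.25 (24 of 25 members) and interferon genes by 0.54 (34 of 38), both at the 100th percentile of random lists. P53 targets (−0.21, percentile 12.7) and cholesterol genes (0.069, percentile 83.0) stayed inside the random range. Matrix (−0.22, 24 of 30 members lower), quiescence (−0.29) and immediate early genes (−0.23, 18 of 25) were lower in the Cas9-rich cells, so these cells also differed in state, and which came first stays open.

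A hypothesis formed after the result was seen, with both of its tests, concerns Hba-a2, an alpha-globin gene (chromosome 11, 32296489 to 32297298), which was 128 (73.2–249) times higher in LNP-CRISPR bulk cells, at 1174 against 12 UMIs. The other haemoglobin genes had a ratio of 1.33, which argues against blood. A candidate explanation is that the delivered Cas9 RNA carries a globin-derived end that was counted as Hba-a2, as such ends are common in synthetic mRNA. In the 4 bulk groups with at least 1000 Cas9 UMIs, Hba-a2 UMIs per Cas9 UMI were alike, 0.0359 in cluster 1, 0.0364 in FAP-like, 0.0382 in macrophage-like and 0.0396 in tenocyte-like cells, a highest over lowest ratio of 1.10. Several bulk groups with less Cas9 had intervals that included these values. They were pericyte-like (0.0367, 0.0100–0.0940), dendritic-like (0.0622, 0.0310–0.111), neutrophil-like (0.0612, 0.0343–0.101) and T or NK-like cells (0.111, 0.0135–0.401). Against the explanation stand 29 Hba-a2 UMIs in 346 LNP-CRISPR bulk cells without Cas9 and a higher value in bulk satellite-like cells (0.105, 0.0523–0.187). A lower value of 0.0154 (0.0125–0.0186) in kit satellite-like cells, on 6774 Cas9 UMIs, also stands against it. With that kit group the highest over lowest ratio was 2.58, so the explanation stays open.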
